A study of Mus musculus with 2 samples.

How the data were processed

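H3K27ac was measured by ChIP-seq in whole lung of mice on postnatal day 0, in 2 libraries that the labels number as biological replicates 1 and 2 of the same tissue. They form 1 group. Replicate 1 was pooled from 15 mice and replicate 2 from a number of mice not given in the sources used here, each pool holding both sexes, and the labels give a size range of 300 to 500 bp. The p values below describe this pair of pooled libraries, or peaks and genes within them, and do not cover the spread between single animals.

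The starting point was the authors' peak lists. Per the authors' deposited descriptions, each list was made from alignments and a control on the build mm10, with 1 list called on each replicate alone and 1 on both pooled. A replicated list was derived from these and is a subset of the pooled list. The aligner, the peak caller, its version and its threshold are not given in the sources used here, and the control was not analysed here. Each peak carries the fold enrichment over the control, a ratio that the authors deposited. Per the deposited format the lists also hold the −log10 of each peak's p and q, and the offset of the summit. The largest p was 0.01 in replicate 2 and close to it in the other lists. A q of 0.01 or less was reached by 64.1% of the peaks of replicate 1, 75.3% of those of replicate 2, 83.3% of the pooled peaks and 98.8% of the replicated peaks. Fold enrichment and p depend on sequencing depth, so they were used to describe, rank or filter peaks within a list. The exception is the correlation of fold between peaks shared by the replicates, which compares no levels. The lists hold no read counts and the depth is unknown. Fewer or narrower peaks in 1 list can therefore come from its depth, and weak peaks missed in a library were not read as absent.

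The replicated list was the main list, and each value was computed again in each replicate's own list to give a mean and SD over the 2 replicates. Peaks on sequences other than the main chromosomes were left out, namely 8 in replicate 1, 10 in replicate 2, 9 in the pooled and 7 in the replicated list. No peak reached past the end of a chromosome of GRCm38, the assembly that mm10 names, which gave the sequence, and GENCODE release M21 gave the genes. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1, with a random seed of 7.

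Peaks were called overlapping when they shared at least 1 bp. The chance level came from 100 circular shifts of each chromosome's peaks, which also cover assembly gaps, and the smallest p that these can give is 0.0099. A peak was a promoter peak when it overlapped 1 kb on either side of any of 41478 TSS of 21911 protein-coding genes. The other peaks were assigned to exon, intron or intergenic sequence by their summit. Acetylated length was the sequence covered by peaks within 25 kb of 1 TSS per gene, the start of the annotated gene. A gene marked at another TSS can therefore have a length of 0, as Camk2a had. The median of a list was compared with 10000 random lists of the same size and the same number of promoter-marked genes, where the smallest two-sided permutation p is 0.0002. Large clusters were formed by joining peaks across gaps up to 12.5 kb, ranked by the sum of width times fold and called large past the tangent point of the ranked curve. A gene was assigned to a cluster when its TSS lay within 10 kb. Shares of genes were compared by two-sided Fisher's exact tests and given 95% Clopper-Pearson intervals, which treat genes as independent. The threshold was an adjusted p of 0.05 with Benjamini-Hochberg adjustment within each family of lists, pairs or motifs.

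Motifs were 26 consensus sequences, searched on either strand in windows reaching 150 bp to either side of the summit of 41833 distal peaks. Each window was paired with the background window closest in GC content among 20 candidates drawn 10 to 50 kb away outside all pooled peaks. Consensus matches name families of factors and do not show binding. Hox genes were measured with 2 kb on either side. The CpG ratio was observed over expected CpG in 1001 bp around the TSS, and random genes for it were drawn from the 200 neighbours on each side in rank of that ratio.

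The 33 gene lists were written from textbook knowledge of cell types and pathways, apart from the olfactory receptors, which were taken by annotated symbol. Of the listed names 502 were matched to the annotation and 2, Cfap144 and Ahsp, were not. The class of lung genes joined 10 lists with 154 genes and that of other organs 8 lists with 122 genes. Epithelial genes were those of the alveolar type 1, alveolar type 2, airway, ciliated and neuroendocrine lists. Endothelial genes were the endothelial and lymphatic lists, mesenchymal genes the mesenchyme, smooth muscle and mesothelial lists, and blood-cell genes the macrophage, lymphoid, neutrophil and mast, and erythroid lists. Globin genes and Ccl21a have near-identical copies and were kept as uncertain.

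The tests, lists, motifs, the naming rule and the alternatives were chosen before the data were examined, apart from 1 alternative, distal peaks only, and the follow-up tests of the closing section. The naming rule took 24 fixed genes, the 2 members of each list with the most acetylated sequence and up to 2 members without a promoter peak in alphabetical order. It also took the 10 top clusters, the 5 strongest replicated peaks and the 5 strongest peaks of each replicate without overlap. Names outside the rule were chosen after their values were seen. They are Camk2a, Cd79b, Chad, Cyp2f2, Dazl, Flt4, Ikzf1, Krt19, Lck, Myl4, Tbx1, Tnni2 and Upk1b, which complete short counts, further members of the Hox clusters, the non-coding genes Malat1 and Neat1, Smad6, Fam160a1, Ddc and Ly6e where they are the TSS nearest to a named peak, and the genes of lower-ranked clusters in the closing section.

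The steps named here were tested on simulated data with known answers. Other steps, such as the matching on GC and CpG content and the tests of chromosome X, were not simulated. The overlap step found 59.9% of 39360 peaks where 59.9% had been copied. The test of gene lists at promoters, run on 21911 genes, called 10 of 10 changed lists and 1 of 20 unchanged ones. The acetylated length test called 3 of 10 changed lists and 0 of 20 unchanged ones, so a list it did not call may still differ. Joining 6000 peaks recovered all 3500 clusters and the 500 large ones. Motif counts in 20000 windows of random sequence found an AP-1 excess of 9.555% where 9.502% had been planted and called 0 of 25 other motifs. The background there was random sequence too, so false calls against genomic windows were not tested.

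The alternatives changed 1 choice at a time. A replicate was left out by using the strongest peaks of the other replicate's list by −log10 p, as many as the replicated list holds. The other lists were the pooled list, replicated peaks with −log10 q of at least 2 and the stronger 50% of replicated peaks by fold. Promoters were also defined by narrower and wider windows and by 1 TSS per gene, and lengths within 10 kb and 50 kb. Clusters were also formed with gaps up to 5 kb, ranked by covered sequence, taken as the top 1000 or assigned by a TSS inside. Motifs were also counted without GC matching, in windows of 75 bp on either side and at the centre of the peak. Replicates were also compared with 50% reciprocal overlap, with the summit inside the other peak, with −log10 q of at least 2 and in the strongest 20000 and 40000 peaks. Genes other than protein-coding ones entered no test.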

Results

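The data describe histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, in whole lung of mice on postnatal day 0. Chromatin immunoprecipitation and sequencing (ChIP-seq) was carried out on 2 biological replicates of 1 group, H3K27ac newborn lung. Replicate 1 was pooled from 15 mice and replicate 2 from an unstated number of mice, with both sexes in each pool. The series holds 1 peak list per replicate, a pooled list and a replicated list, all on the mouse build mm10. Replicate 1 held 103742 peaks with a median width of 278 bp, and replicate 2 held 97407 peaks with a median width of 297 bp. The pooled list held 105935 peaks, of which the replicated list held 56244, covering 51.6 Mb or 1.89% of the genome. Read depth was unknown, so no interval that needs it was given. With a single group, the comparisons were between the replicates, between genomic regions and between groups of genes within this tissue.

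The replicates were compared first, to ask which acetylated regions both pools of animals held. Of the replicate 1 peaks on the main chromosomes, 65158 of 103734 (62.8%) overlapped a replicate 2 peak. In the other direction, 62068 of 97397 replicate 2 peaks (63.7%) overlapped a replicate 1 peak. The mean of these 2 directions was 63.3%, and as they belong to 1 comparison, no SD over replicates is given. Lists shifted at random along the chromosomes overlapped for 3.22% and 3.36% of peaks (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). Peaks held by both were stronger and wider. The median fold enrichment of overlapping against other peaks was 4.36 against 3.27 in replicate 1 and 4.23 against 3.25 in replicate 2, and the median width was 395 bp against 199 bp and 423 bp against 209 bp. In the strongest decile of each list all but 1 peak overlapped, while in the weakest decile 32.6% and 34.3% did. When each peak had to cover 50% of the other, the mean share was 37.6%, against 0.637% in shifted lists. Among 38239 peaks that paired one to one, fold enrichment correlated with Spearman's rho 0.664, and its log2 values with Pearson's r 0.856. These correlations are across peaks, which are not independent replicates.

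**Figure D1:**
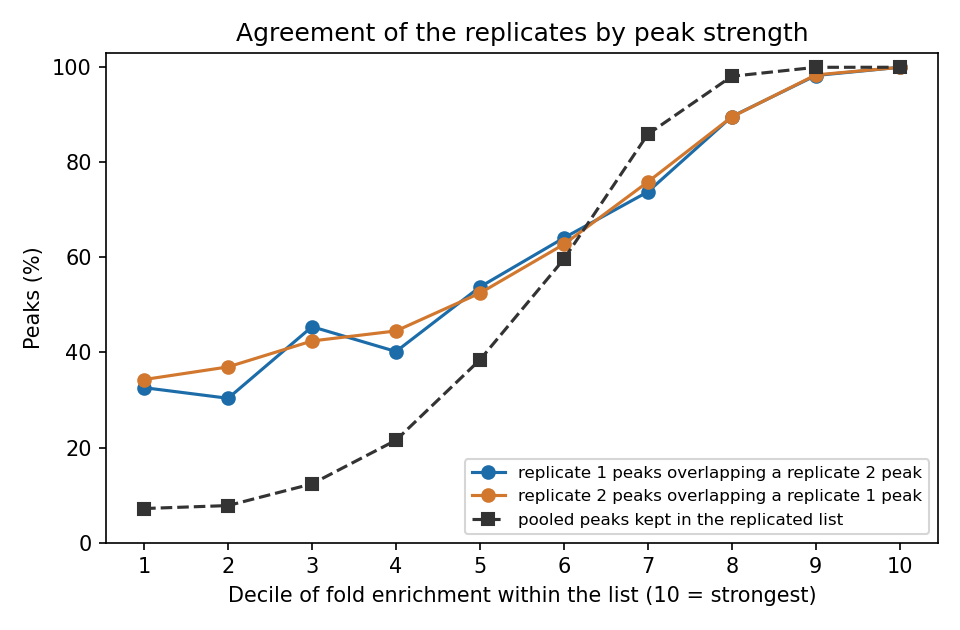
Share of peaks, in percent, overlapping the other replicate by at least 1 bp, in each decile of the authors' fold enrichment within a list (1 line per replicate), and share of pooled peaks kept in the replicated list (dashed line). The overlap rises from 32.6% and 34.3% in the weakest decile to 99.99% in the strongest, and the share kept rises from 7.16% to 100%.

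The 5 strongest peaks without overlap in the other replicate were listed for each replicate. In replicate 1 the strongest lay at the promoter of Naxe, an NAD(P)HX epimerase (chromosome 3, 88058157 to 88058547, fold 8.73). The next 4 lay in the annotated gene Gm37240 with Fam160a1 as the nearest transcription start site (TSS), in an intergenic region 111390 bp from the TSS of Smad6, an inhibitory SMAD of the BMP pathway, 9753 bp from the TSS of Ddc, the aromatic amino acid decarboxylase, and in Adamtsl1. In replicate 2 the strongest lay in Hip1r (chromosome 5, 123979355 to 123979896, fold 9.10), followed by peaks in Dnajc7, in Eva1c, 13568 bp from the TSS of Ly6e and at the promoter of S100a14. The folds of these 10 peaks ran from 6.86 to 9.10.

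The replicated list was compared with the pooled list to see what the authors' selection had kept. All 56244 replicated peaks had the coordinates and fold of a pooled peak. They were 53.1% of the pooled peaks and held 80.2% of the pooled base pairs. Kept peaks had a median fold of 4.37 and a median width of 630 bp, against 2.75 and 229 bp for the 49691 dropped peaks. A looser rule asked for a peak of each replicate whose overlap reached at least 50% of either the pooled or the replicate peak. All 50406 pooled peaks that met it were kept. Of the kept peaks 90.03% overlapped peaks of both replicates' own lists, and 5838 did not meet the 50% rule. Not every replicated peak was therefore called in each replicate alone. Among the dropped peaks, 17453 overlapped replicate 1 only, 18052 replicate 2 only, 13577 neither and 609 both.

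Acetylation was concentrated at promoters. In the replicated list 14404 of 56237 peaks (25.6%) overlapped a window of 1 kb on either side of a protein-coding TSS, against 2.97% in shifted lists, an 8.62-fold excess. In the replicates' own lists the share was 19.1% ± 0.186 (SD, n = 2). Outside promoters, 3.03% of all peaks had their summit in an exon, 44.5% in an intron and 26.9% between genes, against 2.35%, 35.6% and 59.1% in shifted lists (one-sided permutation p = 0.0099 for each class, the smallest possible). Promoter peaks were wider than distal peaks, with medians of 959 bp and 564 bp, a ratio of 1.70, and stronger, with median folds of 8.04 and 4.11. The width ratio was 2.08 ± 0.0205 in the replicates' own lists (SD, n = 2). Promoter peaks made up 83.1% of the strongest decile of the replicated list and 9.50% of the weakest. In the pooled list the promoter share was 17.2%, in the stronger 50% of the replicated peaks it was 40.1%, and both lay above shifted lists (one-sided permutation p = 0.0099).

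The 5 strongest peaks all lay at promoters. They belonged to Klf7, a Krüppel-like transcription factor (chromosome 1, 64118100 to 64122853, fold 64.04), Pnrc1, a nuclear receptor coactivator (chromosome 4, 33246950 to 33249632, fold 62.6), Kmt5b, a histone H4 lysine methyltransferase (chromosome 19, 3766917 to 3769635, fold 59.6), Per1, a core clock gene that glucocorticoids also induce (chromosome 11, 69095097 to 69100634, fold 59.5), and the facing genes Rhof and Setd1b (chromosome 5, 123131383 to 123144364, fold 59.2). At the level of genes, 11573 of 21911 protein-coding genes (52.8%) carried a replicated peak within 1 kb of a TSS. The share was 55.0% ± 0.2001 in the replicates' own lists (SD, n = 2).

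Gene lists fixed in advance were then compared with all other protein-coding genes, to see which cell types and pathways the promoter mark covered. Of 33 lists, 9 were marked more often than other genes and 16 less often (two-sided Fisher's exact test, Benjamini-Hochberg adjustment over the lists). Absence of a promoter peak refers to the replicated list, and of the genes named for it below, Cox4i2 and Dcn had one in replicate 1 and Bmp4, Car4, Cd19, Col14a1 and Hoxb8 in replicate 2. Genes of the gas-exchange epithelium were among those marked more often. All 15 alveolar type 2 genes were marked (95% Clopper-Pearson interval 78.2% to 100%, adjusted exact p = 2.70e-04), and so were 16 of 17 alveolar type 1 genes (94.1%, adjusted exact p = 7.61e-04) and all 19 transcription factors of the lung epithelium (adjusted exact p = 3.96e-05). Sftpc and Sftpb encode surfactant proteins, and both had promoter peaks of fold 10.6. Acetylated sequence within 25 kb of the TSS came to 15.4 kb at Sftpc (replicates 13.75 kb ± 1.4998, SD, n = 2), 14.1 kb at Sftpb, 15.1 kb at Lpcat1, which makes surfactant phosphatidylcholine, and 8.41 kb at Abca3, the lipid transporter of lamellar bodies. Of the alveolar type 1 genes, Hopx, a homeodomain cofactor, held 25.1 kb and Ager, the receptor for advanced glycation end products, held 20.2 kb, while Igfbp2, an insulin-like growth factor binding protein, was the 1 member without a promoter peak. Among the transcription factors, Nkx2-1, required for lung specification, held 24.5 kb (replicates 23.9 kb ± 0.214, SD, n = 2) with a promoter peak of fold 20.6 (gene at chromosome 12, 56531958 to 56536908), and Foxa2 held 16.4 kb.

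Of the 5 vascular and mesenchymal lists, 2 were marked more often than other genes. Of 22 endothelial genes 21 were marked (95.5%, adjusted exact p = 8.49e-05), led by Egfl7, a secreted vascular factor with 26.0 kb of acetylated sequence, and Tbx3 with 14.3 kb. Pecam1 and Cdh5, the endothelial junction genes, had promoter peaks of fold 12.4 each, and Car4, a membrane carbonic anhydrase, had none. Of 23 mesenchyme and fibroblast genes 21 were marked (91.3%, adjusted exact p = 4.61e-04), led by the T-box genes Tbx2 with 22.3 kb and Tbx5 with 18.8 kb. Foxf1, Tbx4 and Tcf21, transcription factors of lung mesenchyme, held 14.6 kb, 11.3 kb and 8.08 kb, and Col14a1 and Dcn, matrix genes, had no promoter peak. Smooth muscle and pericyte genes were marked in 11 of 18 cases and did not pass the test (adjusted exact p = 0.679; in the pooled list 0.0392, range 0.0392 to 1.00). Tagln held 12.6 kb and Cox4i2 12.1 kb, the latter within 10 kb of the large cluster that holds Bcl2l1, while Acta2 held 2.78 kb with a promoter peak of fold 5.30 and Cnn1 and Cox4i2 had no promoter peak. The mesothelial list (3 of 8, Krt19, Msln and Upk1b, with the most acetylated sequence at Msln with 11.96 kb and Upk3b with 7.04 kb) and the lymphatic endothelial list (4 of 8, Flt4, Lyve1, Pdpn and Tbx1, with the most at Lyve1 with 7.25 kb and Pdpn with 5.10 kb) were not called either (adjusted exact p = 0.575 and 1.00). Wt1, the mesothelial transcription factor, and the mesothelial genes Bnc1 and Gpm6a had no promoter peak, as had the lymphatic genes Ccl21a and Mmrn1, of which Ccl21a has near-identical copies and is uncertain.

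Airway secretory and basal, neuroendocrine, macrophage, neutrophil and mast cell, and erythroid genes were marked less often than other genes, while ciliated and lymphoid genes did not pass the test. Of 15 airway secretory and basal genes 2 were marked, Cyp2f2 and Chad (adjusted exact p = 0.00456). Scgb1a1, the club cell secretoglobin, had a promoter peak in replicate 1 and none in the replicated list, and 9.94 kb within 25 kb were acetylated, Krt15 held 4.89 kb, and Aqp3 and Bpifa1 had no promoter peak. None of the 11 neuroendocrine genes was marked (95% interval up to 28.5%, adjusted exact p = 6.06e-04). They included Ascl1, the proneural factor, and Calca, which encodes calcitonin gene-related peptide, and the highest acetylated lengths were 3.15 kb at Syp and 2.02 kb at Scg5. Ciliated cell genes were marked in 9 of 17 cases (adjusted exact p = 1.00). They were led by Tppp3 with 9.43 kb and Tubb4b with 8.16 kb, and Foxj1, the regulator of motile cilia, Ccdc39 and Dnah5 had no promoter peak in the replicated list, although Foxj1 had one in replicate 1.

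Of 18 macrophage and myeloid genes 2 were marked (adjusted exact p = 8.90e-04), Cd68 with 14.2 kb and Mpeg1 with 13.7 kb, and neither Ptprc, the pan-leukocyte phosphatase, nor Adgre1 nor C1qa had a promoter peak in the replicated list, and Ptprc had one in replicate 1. Of 11 neutrophil and mast cell genes 1 was marked, Kit (adjusted exact p = 0.00648). Elane held 2.74 kb, and Cma1 and Cpa3 had no promoter peak. Of 15 erythroid genes 2 were marked, Tal1 with 7.78 kb and Nfe2 with 5.76 kb (adjusted exact p = 0.00456), and Alas2, Epb42 and the globin gene Hbb-bs had no promoter peak. Globin genes have near-identical copies and are uncertain. Of 13 lymphoid genes 3 were marked, Cd79b, Ikzf1 and Lck (adjusted exact p = 0.0611). Cd79a held 13.05 kb and Nkg7 4.04 kb, and Bcl11b and Cd19 had no promoter peak. The lymphoid list passed the threshold in 4 of 8 alternative settings, among them without replicate 1 (adjusted exact p = 0.0164, range 0.0164 to 0.0704). Promoters of the airway and blood-cell genes were poor in CpG, with a median observed over expected ratio of 0.1997 against 0.558 for all genes, while the median of the neuroendocrine genes was 0.573. Against random genes of like CpG content the neuroendocrine list stayed lower (adjusted permutation p = 9.14e-04), and the airway, macrophage, neutrophil and mast, and erythroid lists did not pass (adjusted permutation p = 0.234, 0.117, 0.594 and 0.355).

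Genes of organs that were not sampled were seldom marked. All 8 organ lists lay below other genes, namely skeletal muscle (2 of 17, adjusted exact p = 0.00156), hepatocyte (0 of 19, adjusted exact p = 1.04e-05), neuron (1 of 20, adjusted exact p = 5.37e-05), kidney nephron (0 of 14, adjusted exact p = 1.11e-04), intestinal epithelium (0 of 13, adjusted exact p = 2.10e-04), pancreas (1 of 15, adjusted exact p = 6.50e-04), germ cell (1 of 16, adjusted exact p = 4.50e-04) and thyroid follicular cell (0 of 8, adjusted exact p = 0.00426). The marked genes were Tnni2, Mylpf, Camk2a, Cela1 and Dazl. The replicated list held no promoter peak at Alb, the albumin gene, Afp, Ahsg, Myod1, the myogenic regulator, Acta1, Cacna1s, Neurod1, Dlx1, Dlx2, Ins2, Cela2a, Cpa1, Tg, the thyroglobulin gene, Duox2, Foxe1, Aqp2, Avpr2, Alpi, Apoa4, Acrv1 or Ddx4, although Cpa1 had one in each replicate's own list. The highest acetylated lengths in these lists were 10.6 kb at Cdx1, 8.54 kb at Apoa2, 7.64 kb at Vil1, 7.16 kb at F2, 7.13 kb at Mylpf, 7.03 kb at Tnnt3, 6.61 kb at Cpa1, 6.46 kb at Aqp2, 5.42 kb at Zp3, 4.66 kb at Stra8, 4.34 kb at Slc5a5, 3.35 kb at Slc17a7, 3.04 kb at Slc5a2, 2.41 kb at Cela1 and 1.43 kb at Grin1. These lengths can include peaks of neighbouring genes. Cdx1, Apoa2 and Aqp2 had no promoter peak in the replicated list, although Apoa2 had one in replicate 1. The marked alveolar type 1 gene Aqp5 lies within 25 kb of the TSS of Aqp2. The thyroid call was lost without replicate 2 (adjusted exact p = 0.0502, range 0.0035 to 0.0502 over 8 alternatives). Cardiomyocyte genes, of the neighbouring heart, were marked in 2 of 14 cases, Myl4 and Myh7 (adjusted exact p = 0.00729). Myh7 held 4.09 kb and Tnni3 4.01 kb, and Myh6, Actc1 and Mybpc3 had no promoter peak. Of 1092 olfactory receptor genes 3 were marked (0.275%, interval 0.0567% to 0.801%, replicates 0.412% ± 0.0647, SD, n = 2).

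In the direct comparison, 102 of 154 lung cell-type genes (66.2%, interval 58.2% to 73.6%) and 5 of 122 genes of other organs (4.10%, interval 1.34% to 9.31%) carried the promoter mark (two-sided Fisher's exact p = 1.73e-29). In the replicates' own lists the shares were 69.8% ± 0.459 and 7.38% ± 1.16 (SD, n = 2). Within the lung, endothelial genes were marked in 25 of 30 cases (83.3%), mesenchymal genes in 35 of 49 (71.4%), epithelial genes in 42 of 75 (56.0%) and blood-cell genes in 8 of 57 (14.04%). Of the 6 pairs, 4 differed (two-sided Fisher's exact test, adjusted over the pairs). The epithelial share joins alveolar type 2 (15 of 15) and type 1 genes (16 of 17) with airway (2 of 15), neuroendocrine (0 of 11) and ciliated genes (9 of 17). Endothelial genes were marked more often than this joint class (adjusted exact p = 0.0189), and blood-cell genes less often than endothelial (adjusted exact p = 1.39e-09), mesenchymal (adjusted exact p = 3.94e-09) and epithelial genes (adjusted exact p = 1.34e-06). Endothelial and mesenchymal genes, and epithelial and mesenchymal genes, did not pass the test (adjusted exact p = 0.285 and 0.110). These comparisons were not matched on CpG content. Against random genes of like CpG content, none of the 4 blood-cell lists passed singly (adjusted permutation p from 0.117 to 0.99). The endothelial list and the mesenchyme and fibroblast list lay above such genes (adjusted permutation p = 9.14e-04 for both).

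**Figure D2:**
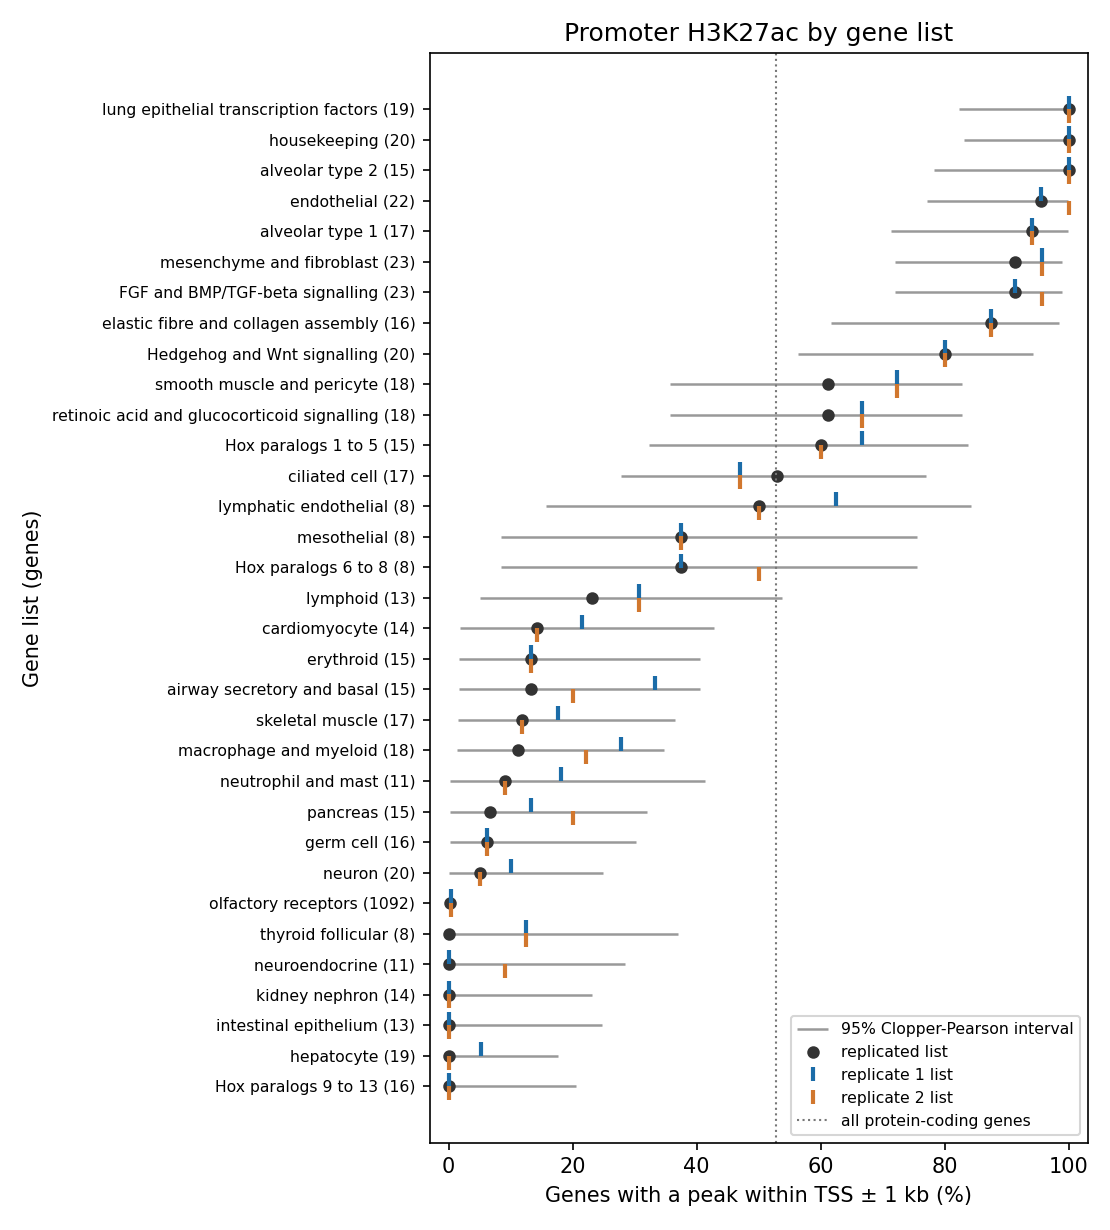
Percent of the genes of each list with a peak within 1 kb of a TSS, with the number of genes in parentheses. Dots are the replicated list with 95% Clopper-Pearson intervals, ticks are the replicates' own lists, and the dotted line is the share of all protein-coding genes (52.8%). Lung epithelial transcription factors, housekeeping and alveolar type 2 genes stand at 100%, and hepatocyte, kidney and intestinal genes at 0%.

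Of the signalling and matrix lists, FGF and BMP/TGF-beta and elastic fibre and collagen genes were marked more often than other genes, Hedgehog and Wnt genes with a less stable call, and retinoic acid and glucocorticoid genes did not pass the test. Of 23 FGF and BMP/TGF-beta signalling genes 21 were marked (91.3%, adjusted exact p = 4.61e-04), with 25.5 kb at Smad7, an inhibitor of TGF-beta signalling, and 18.5 kb at Dusp6, an ERK phosphatase, and no promoter peak at Bmp4 or Etv4. Of 16 elastic fibre and collagen assembly genes 14 were marked (87.5%, adjusted exact p = 0.00729), with 26.6 kb at Lama5, a laminin chain, and 18.05 kb at Col4a1, a basement membrane collagen, and no promoter peak at Loxl2 or Nid1. Of 20 Hedgehog and Wnt signalling genes 16 were marked (adjusted exact p = 0.0297), with 13.6 kb at Lrp5, a Wnt co-receptor, and 12.9 kb at Ptch1, the Hedgehog receptor, and no promoter peak at Rspo2 or Sfrp1. This call was kept in 3 of 8 alternatives and was lost without either replicate (adjusted exact p = 0.0534 and 0.0550, range 0.0175 to 0.0560), and against genes of like CpG content (80.0% against 75.5%) the list did not pass the test (adjusted permutation p = 0.955). Of 18 retinoic acid and glucocorticoid signalling genes 11 were marked (adjusted exact p = 0.679), with 26.0 kb at Rara and 16.9 kb at Rarg, retinoic acid receptors, and no promoter peak at Aldh1a2 or Crabp1. All 20 housekeeping genes were marked (adjusted exact p = 3.44e-05), with 14.8 kb at Actb, the beta-actin gene, and 12.52 kb at Eef2, a translation elongation factor.

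Acetylated length around the TSS was compared next, among genes with the same promoter status, since promoter peaks alone do not show how much sequence is marked. Of 33 lists, 9 had a longer median within 25 kb of the TSS than 10000 random lists matched on promoter peak, and 0 a shorter one (two-sided permutation test, Benjamini-Hochberg adjustment over the lists, 12 and 0 at an unadjusted p below 0.05). Lists whose random lists had a median of 0 kb, such as the neuroendocrine and hepatocyte lists, could not come out shorter. The medians were 8.76 kb for alveolar type 2 genes (random lists 3.03 kb, adjusted permutation p = 0.00924), 7.23 kb for alveolar type 1 genes (2.89 kb, adjusted permutation p = 0.011), 6.603 kb for lung epithelial transcription factors (3.05 kb, adjusted permutation p = 0.019), 6.99 kb for mesenchyme and fibroblast genes (2.80 kb, adjusted permutation p = 0.00165) and 7.49 kb for FGF and BMP/TGF-beta genes (2.80 kb, adjusted permutation p = 0.00165). Hox paralogs 1 to 5 (20.7 kb), Hox paralogs 6 to 8 (9.68 kb), housekeeping genes (6.43 kb) and germ cell genes (1.18 kb) were also longer. In the replicates' own lists the alveolar type 2 median was 7.57 kb ± 0.714 and the mesenchymal median 5.64 kb ± 0.0721 (SD, n = 2). Elastic fibre and collagen genes (5.29 kb, random lists 2.70 kb, adjusted permutation p = 0.0673) were not called, but were without replicate 1 (adjusted permutation p = 0.0165) and without replicate 2 (adjusted permutation p = 0.0388, range 0.00566 to 0.247). Endothelial genes (4.94 kb, adjusted permutation p = 0.0913) were called with windows of 10 kb (adjusted permutation p = 0.0011, range 0.0011 to 0.634). Windows of neighbouring genes overlap, and the length includes the promoters of neighbours. The mesenchymal call was lost without replicate 1, where the median exceeded that of random lists by only 1.92 kb (adjusted permutation p = 0.0528). It was also lost with windows of 50 kb (adjusted permutation p = 0.0904, range 0.0011 to 0.0904), where the alveolar type 2 and transcription factor calls were lost too. With distal peaks alone, chosen after seeing the data, the medians of the germ cell and housekeeping lists were 0 kb and 0.529 kb and neither was called (adjusted permutation p = 1.00 for both), while alveolar type 2 genes kept 5.11 kb (random lists 0.607 kb, adjusted permutation p = 0.00165). The airway secretory and basal (1.18 kb, random lists 0 kb), endothelial (2.72 kb, 0.536 kb) and Hedgehog and Wnt lists (1.88 kb, 0.327 kb) were longer in this setting (adjusted permutation p = 0.0066, 0.0066 and 0.0277) and not with all peaks (adjusted permutation p = 0.0913, 0.0913 and 0.748). The housekeeping call was also lost in the stronger 50% of peaks (adjusted permutation p = 0.102) and with windows of 10 kb and 50 kb (adjusted permutation p = 0.0678 and 0.122, range 0.0157 to 1.00 over 8 alternatives).

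Large domains of acetylation were formed by joining neighbouring peaks. The 56237 replicated peaks formed 18567 clusters, of which 943 were large by the tangent of the ranked curve of width times fold. These 943 clusters had a median length of 36.2 kb and a median of 10 peaks, and they held 20.4% of the peaks and 28.9% of the acetylated sequence. The highest-ranked cluster (chromosome 19, 5770626 to 5852774) held the TSS of Scyl1 and the non-coding genes Malat1 and Neat1, abundant nuclear RNAs that were covered over 88.5% and 89.9% of their length. The next ranks held Tns1, a focal adhesion gene (chromosome 1, 73987208 to 74093174), Trim8 (chromosome 19, 46447355 to 46534027), Rhof and Setd1b (chromosome 5, 123110594 to 123151180), a region with Sbno2, Stk11, Cbarp, Atp5d, Midn, Cirbp and 1600002K03Rik (chromosome 10, 80070428 to 80173904) and a region with Med24, Thra, Nr1d1, Msl1 and Casc3 (chromosome 11, 98707836 to 98810875). Sik1, a salt-inducible kinase (chromosome 17, 31814939 to 31944735), Btg2, an antiproliferative gene (chromosome 1, 134054763 to 134106810), Bcl2l1, an inhibitor of apoptosis (chromosome 2, 152763614 to 152831765), and Chd2, a chromatin remodeller (chromosome 7, 73517333 to 73625168), completed the first 10.

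Lung genes lay near large clusters more often than genes of other organs, in 25 of 154 (16.2%, interval 10.8% to 23.0%) against 1 of 122 cases (0.82%, interval 0.0208% to 4.48%), the latter being Apoa2 (two-sided Fisher's exact p = 3.62e-06). In the replicates' own lists the shares were 21.4% ± 2.75 and 0.82% ± 0 (SD, n = 2). The comparison was not matched on promoter peaks, which 102 of 154 lung genes and 5 of 122 genes of other organs carried. Of the 10 lung lists only 2, alveolar type 2 and alveolar type 1, were called against all other genes, so the excess is not shown for lung genes in general. Against all other genes, of which 8.21% lay within 10 kb of a large cluster, 8 lists were higher and 1 lower. Lists other than the olfactory receptors were too small to be called lower at this share. Even 0 of 20 neuron genes gave an unadjusted two-sided Fisher's exact p = 0.403. The higher lists were alveolar type 2 (7 of 15, among them Sftpc, Sftpb and Lpcat1, adjusted exact p = 5.73e-04), alveolar type 1 (7 of 17, among them Ager and Hopx, adjusted exact p = 9.54e-04), lung epithelial transcription factors (7 of 19, among them Nkx2-1 and Foxa2, adjusted exact p = 0.0019), FGF and BMP/TGF-beta signalling (9 of 23, adjusted exact p = 3.87e-04), retinoic acid and glucocorticoid signalling (8 of 18, among them Rara, Rarg and Per1, adjusted exact p = 3.87e-04), housekeeping genes (8 of 20, adjusted exact p = 5.73e-04), Hox paralogs 1 to 5 (9 of 15, adjusted exact p = 8.70e-06) and Hox paralogs 6 to 8 (5 of 8, adjusted exact p = 7.93e-04). The lower list was the olfactory receptors (0 of 1092). Mesenchyme and fibroblast genes (4 of 23) and endothelial genes (3 of 22) did not pass the test (adjusted exact p = 0.316 and 0.865), although the mesenchymal list did without replicate 1 (adjusted exact p = 0.0063, range 0.00312 to 0.577 over 9 alternatives) and the endothelial list did when clusters were ranked by covered sequence (adjusted exact p = 0.00949, range 0.00949 to 0.862). Elastic fibre and collagen genes (4 of 16, adjusted exact p = 0.111) also passed without replicate 1 (adjusted exact p = 0.0211, range 0.0144 to 0.126). Hedgehog and Wnt genes (5 of 20, adjusted exact p = 0.0669) passed in the pooled list (adjusted exact p = 0.0438) and with gaps up to 5 kb (adjusted exact p = 0.0358, range 0.0358 to 0.261). The call of Hox paralogs 6 to 8 was lost without replicate 2 (adjusted exact p = 0.0594, range 7.36e-04 to 0.0676), and that of alveolar type 2 genes with stitching gaps up to 5 kb (adjusted exact p = 0.2, range 1.40e-05 to 0.2). Between lung compartments, 0 of 6 pairs differed at large clusters after adjustment by Fisher's exact test, and 1 did at an unadjusted p, epithelial (16 of 75) against blood-cell genes (4 of 57, p = 0.0276).

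The Hox genes, which set position along the body axis, were marked by cluster and by paralog. All 9 marked genes of paralogs 1 to 5 were Hoxa1 to Hoxa5 and Hoxb2 to Hoxb5, out of 15 genes (60.0%, interval 32.3% to 83.7%). None of the 16 genes of paralogs 9 to 13 was marked (interval up to 20.6%, two-sided Fisher's exact p = 2.48e-04 between the sets). Of paralogs 6 to 8, Hoxa6, Hoxb6 and Hoxb7 were marked and Hoxa7 and Hoxb8 were not. Acetylation covered 92.4% of Hoxa2 with 2 kb on either side (replicates 90.3% ± 0.419, SD, n = 2), 87.2% of Hoxb4 (83.4% ± 1.36) and 84.2% of Hoxa5 (81.2% ± 2.61), and fell to 11.01% at Hoxa7 and 0% at Hoxa9. The largest acetylated lengths within 25 kb were 40.8 kb at Hoxb3 and 36.3 kb at Hoxb4, with 18.6 kb at Hoxa6, 16.9 kb at Hoxb6, 4.84 kb at Hoxa9 and 2.24 kb at Hoxb9. Hoxb1 and Hoxc4 had no promoter peak, nor had Hoxa10 or Hoxa11. No gene of the Hoxc or Hoxd cluster held a replicated promoter peak, and Hoxc4 held one in replicate 1 only. Genes of a Hox cluster adjoin each other and share peaks, so they are not independent.

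**Figure D3:**
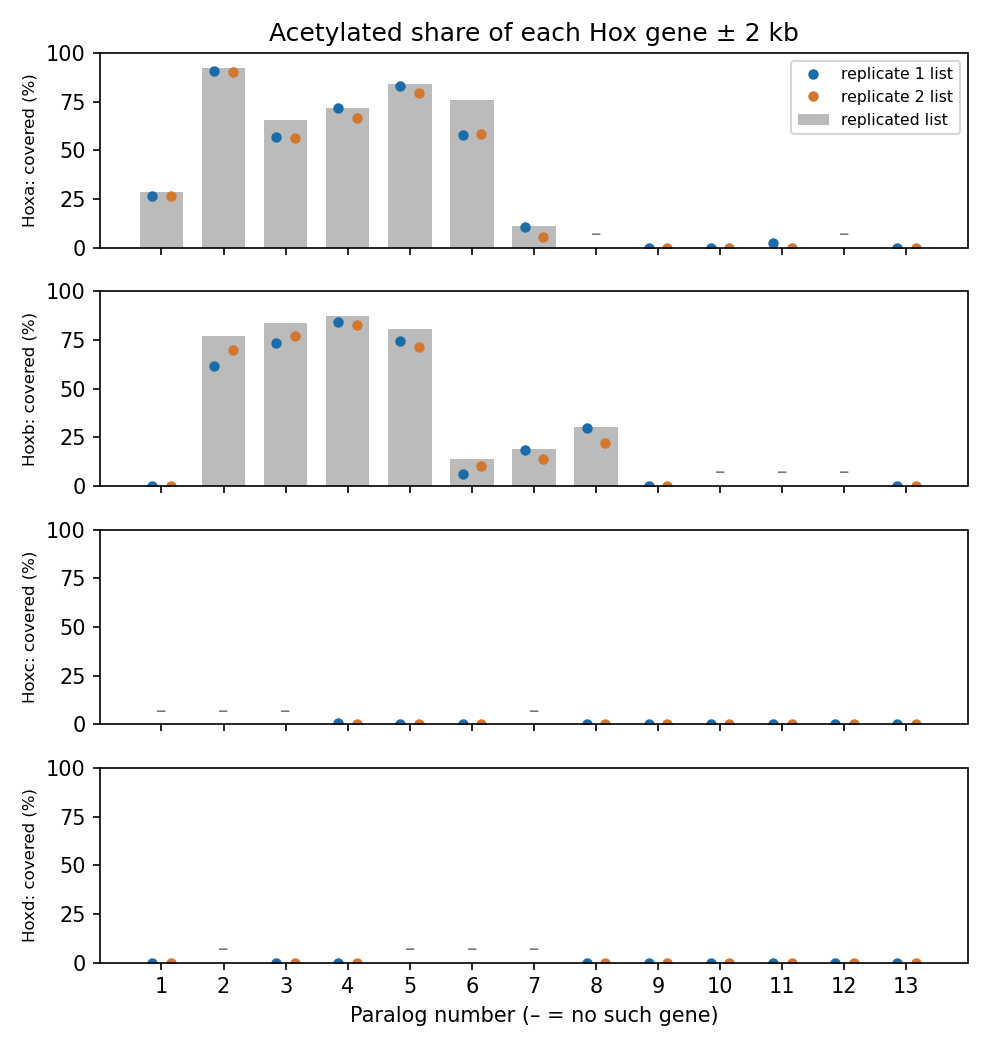
Acetylated share, in percent, of each Hox gene with 2 kb on either side, by paralog number and cluster. Bars are the replicated list and dots the replicates' own lists, and a dash marks a paralog that does not exist. Coverage is high from Hoxa2 to Hoxa6 and from Hoxb2 to Hoxb5 and 0% in the replicated list for all Hoxc and Hoxd genes.

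Sequence motifs in distal peaks were compared with nearby windows of like GC content, to see which families of transcription factor sites marked regions held. Of 26 consensus motifs in 41833 windows reaching 150 bp to either side of the peak summit, 12 were more frequent and 5 less frequent than in as many background windows (two-sided Fisher's exact test, Benjamini-Hochberg adjustment over the motifs). The mean GC content was 49.4% and 48.8%. ERG-like ETS sites, which name a family of factors and no single cell type, were found in 4.89% of windows against 3.39%, a ratio of 1.44 (adjusted exact p = 3.97e-26, replicates 1.37 ± 0.0515, SD, n = 2). Forkhead sites, shared by FOXA and FOXF factors, were found in 4.71% against 3.39%, a ratio of 1.39 (adjusted exact p = 3.23e-21, replicates 1.41 ± 0.0301). TEAD sites (ratio 1.25, adjusted exact p = 2.87e-11), SOX sites (1.21, adjusted exact p = 4.45e-13) and the E-box CAGCTG (1.21, adjusted exact p = 6.46e-17) were also higher. These 5 motifs were called higher, and the E-box CAGATG lower (0.885, adjusted exact p = 3.66e-06), in all 8 alternatives.

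Other motif calls were less stable. Glucocorticoid receptor sites (ratio 1.44, adjusted exact p = 1.95e-04), ETS sites (1.53, adjusted exact p = 3.65e-04), RUNX (1.23, adjusted exact p = 2.64e-05), GATA (1.15, adjusted exact p = 1.76e-04), GRHL (1.14, adjusted exact p = 0.0123), KLF/SP (1.06, adjusted exact p = 0.0342) and MEF2 (1.82, adjusted exact p = 0.0237) were higher, and each lost its call in at least 1 alternative. The glucocorticoid receptor call was made in only 4 of 8 alternatives, with ratios down to 1.101, and the MEF2 call in 3 of 8, with ratios down to 1.13, and both were lost among replicated peaks with −log10 q of at least 2 (ratios 1.17 and 1.61, adjusted exact p = 0.0988 and 0.0684). Without GC matching the ratio of GRHL was 0.998 and with windows of 75 bp on either side that of KLF/SP was 0.949. The NKX2-1 site was slightly less frequent than in the background (ratio 0.962, adjusted exact p = 0.0138), but without GC matching its ratio was 1.02 (adjusted exact p = 0.366, range 1.38e-05 to 0.913). T-box (0.869, adjusted exact p = 0.0243), POU (0.866, adjusted exact p = 0.0384) and CTCF sites (0.367 from 11 and 30 windows, adjusted exact p = 0.0102) were lower in the summit windows, and these calls too were lost in some alternatives. Without replicate 1 the calls of KLF/SP (adjusted exact p = 0.238) and CTCF (adjusted exact p = 0.0588) were lost, and without replicate 2 that of MEF2 (adjusted exact p = 0.0776), whose ratios in the replicates' own lists were 1.34 ± 0.293 (SD, n = 2). AP-1 (1.03, adjusted exact p = 0.401) and C/EBP (1.61, adjusted exact p = 0.0574) were not called at summits in the replicated list. In the pooled list both were higher (1.05, adjusted exact p = 0.013, and 1.49, adjusted exact p = 0.0113), and AP-1 was also higher without GC matching (1.09, adjusted exact p = 0.0105). In windows at the centre of the peak their ratios were 1.11 (adjusted exact p = 2.76e-04, range 2.76e-04 to 0.977) and 2.85 (adjusted exact p = 5.34e-06, range 5.34e-06 to 0.623). Within 75 bp of the summit AP-1 was lower (0.881, adjusted exact p = 0.00751). The C/EBP call was also made without replicate 2 (adjusted exact p = 0.00788). HNF1, HNF4A, CDX, PU.1, NF1, the CArG box and RFX did not pass the test (adjusted exact p from 0.18 to 1.00). RFX was lower without replicate 2 (0.578, adjusted exact p = 0.00188, range 0.00188 to 0.676) and in the pooled list (0.689, adjusted exact p = 0.00401). PU.1 was higher without GC matching (1.30, adjusted exact p = 0.00105, range 0.00105 to 0.902) and at the peak centre (1.17, adjusted exact p = 0.0299). The CArG box was lower without GC matching (0.821, adjusted exact p = 0.00133, range 0.00133 to 0.944) and within 75 bp of the summit (0.8125, adjusted exact p = 0.0369).

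**Figure D4:**
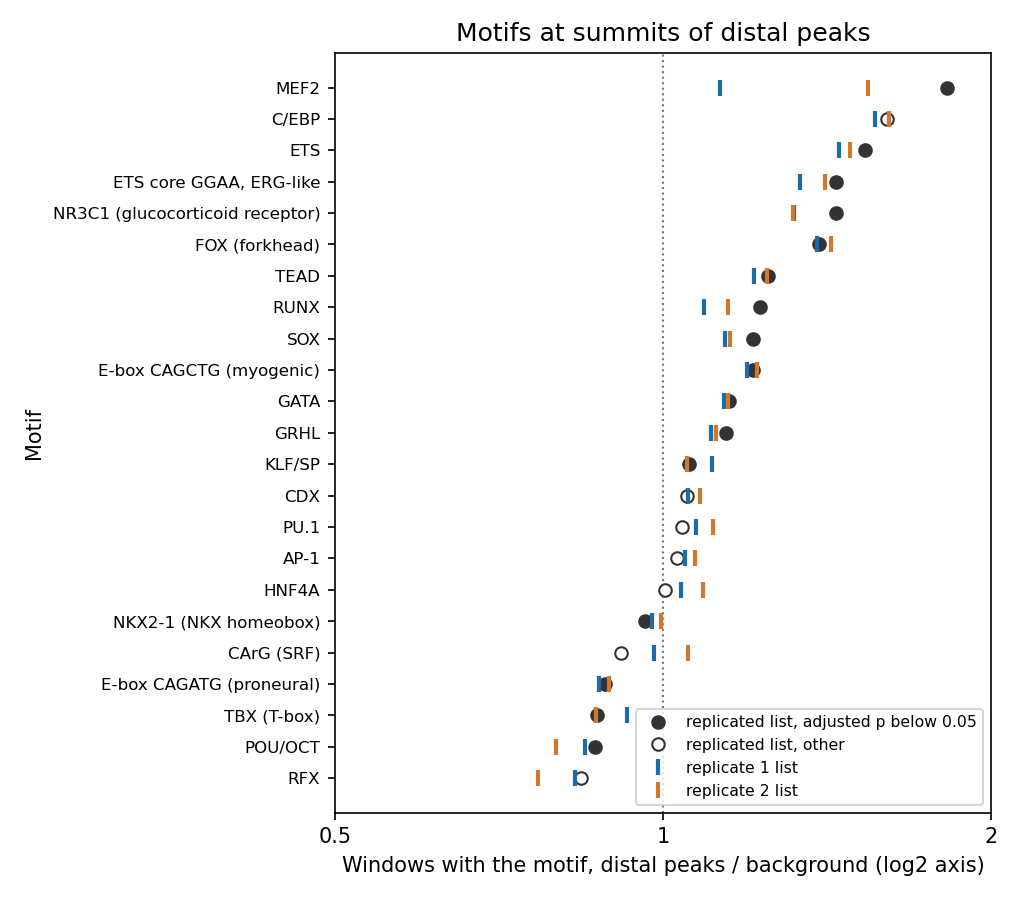
Ratio of the share of distal summit windows holding each consensus to the share of GC-matched background windows, on a log2 axis. Filled dots are motifs with an adjusted p below 0.05 in the replicated list, open dots the others, and ticks are the replicates' own lists. Motifs found in fewer than 50 windows of both sets together are not drawn. ERG-like ETS and forkhead sites lie at 1.44 and 1.39.

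Chromosome X carried few peaks. It held 854 replicated peaks, 4.99 per Mb, while autosomes ran from 16.1 per Mb on chromosome 14 to 37.6 per Mb on chromosome 11. The density of X was 0.223 of the autosomal median (0.211 ± 0.0295 in the replicates' own lists, SD, n = 2). Its density of protein-coding genes, 5.54 per Mb, was 0.71 of the autosomal median, and 33.4% of its genes had a promoter peak against 43.6% to 62.1% on autosomes. For each marked gene X held 1.47 distal peaks, and autosomes 3.08 to 4.81. The Y chromosome held 2 peaks.

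**Figure D5:**
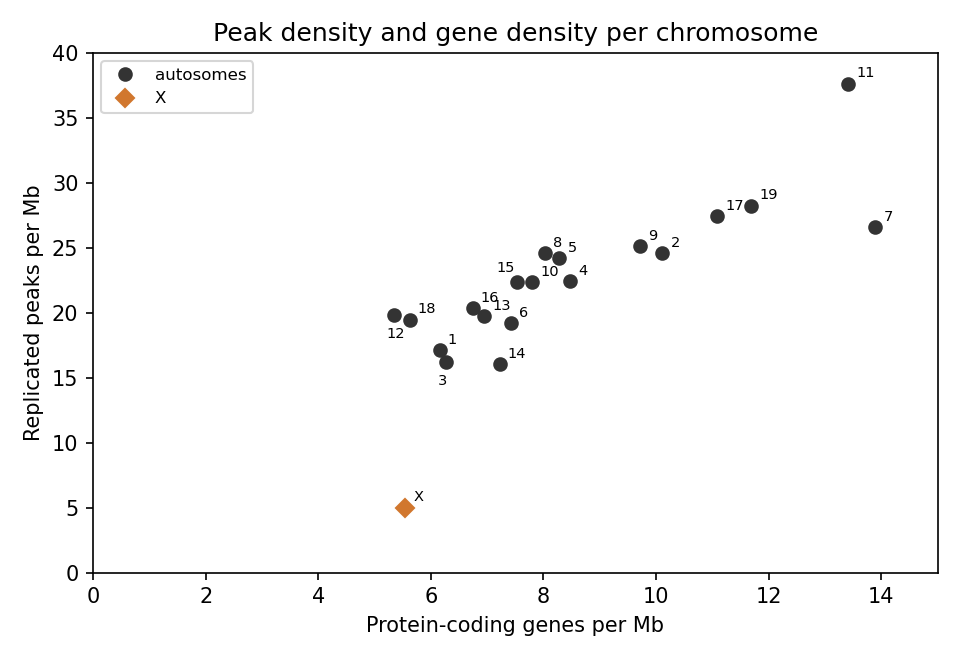
Replicated peaks per Mb against protein-coding genes per Mb for the 19 autosomes (circles) and chromosome X (diamond), each point being 1 chromosome. X lies at 4.99 peaks per Mb, below all autosomes (16.1 to 37.6), including those of like gene density.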

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

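Of these alternatives 1, distal peaks only, was chosen after the data were seen. Of 173 values that answer a comparison 153 stayed the same under an alternative, 20 moved and 0 reversed. For a test, the same meant the same direction and side of the threshold, whatever the change in size. For a count it meant a change within a fixed factor, and for other values a change below the SD between replicates, or none. The replicate overlap, 63.3%, thus counted as the same although it lay between 37.6% and 81.3% in 5 alternatives. The promoter share, which also counted as the same, lay between 17.2% and 40.1% and above shifted lists in all 8 alternatives (one-sided permutation p = 0.0099). Lung genes exceeded genes of other organs by 51.3 to 66.6 percentage points at promoters in 8 alternatives and by 13.5 to 22.05 at large clusters in 9, each past the threshold. The 4 calls between compartments at promoters and the Hox test held in all 5 alternatives run for each. Of 825 values of single lists 751 were the same, 17 lost and 25 gained a call and 32 reversed. Of 208 motif values 154 were the same, 22 lost and 12 gained a call and 20 reversed. Of 168 lengths of single genes 79 moved, and of 84 values of compartment pairs 3 reversed. Except where the construction is named, the cause was not tested.

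Values that moved were these. The rise in replicate overlap from the weakest to the strongest decile, 66.5 percentage points, was 74.3 with 50% reciprocal overlap, 79.6 with the summit inside, 59.3 with −log10 q of at least 2, and 49.05 and 52.35 in the strongest 20000 and 40000 peaks. In the same order the correlation of fold, rho 0.664, was 0.799, 0.783, 0.717, 0.826 and 0.788. The share of pooled peaks kept, 53.1%, was 62.9% at −log10 q of at least 2. The width ratio of promoter to distal peaks, 1.70, was 1.79 to 1.85 without a replicate, 2.26 in the pooled list, 1.30 in the stronger 50%, and 1.80 and 1.54 with TSS windows of 500 bp and 2.5 kb. The density of X relative to autosomes, 0.223, was 0.187 to 0.201 without a replicate. Motifs called lower fell from 5 to 3 without GC matching and to 3 at the peak centre.

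Values that reversed were mostly of lists and motifs without a call, and NKX2-1, KLF/SP and GRHL sites and the length of housekeeping genes were the exceptions. At promoters, the difference from other genes in percentage points changed sign for ciliated genes (main 0.123) to −15.4 to −3.93 without a replicate, −17.5 in the stronger 50%, −5.06 within 500 bp and −1.33 within 2.5 kb. Smooth muscle genes (8.30) went to −0.706 to 10.1 without a replicate and −13.6 in the stronger 50%. Lymphatic genes (−2.82) went to 5.80 in the pooled list, and retinoic acid and glucocorticoid genes (8.30) to −5.95 with 1 TSS per gene. For length, the difference in kb went to −0.028 for ciliated genes in the pooled list, to −0.139 for mesothelial and −0.182 for retinoic acid and glucocorticoid genes within 10 kb, and to −0.0775 for housekeeping genes with distal peaks only, where promoter peaks no longer count.

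At large clusters the difference in percentage points reversed as follows. Ciliated genes (3.56) went to −0.969 with gaps up to 5 kb and −3.24 ranked by covered sequence. Lymphatic genes (−8.21) went to 1.92 in the pooled list and 3.38 by covered sequence. Smooth muscle genes (2.90) went to −2.53 to −1.99 without a replicate, −0.652 in the stronger 50%, −6.86 with gaps up to 5 kb and −2.06 with the TSS inside. Mesothelial genes (−8.21) went to −7.55 to 4.42 without a replicate, 14.4 in the pooled list, 5.65 with gaps up to 5 kb and 3.38 by covered sequence. Lymphoid genes (−0.518) went to −0.391 to 0.148 without a replicate, 1.49 in the stronger 50%, 8.54 with gaps up to 5 kb and 0.0797 with the TSS inside. Macrophage genes (2.90) went to −1.30 with gaps up to 5 kb and erythroid genes (−1.54) to 4.22 by covered sequence. Epithelial minus endothelial genes (11.3) went to −1.33 by covered sequence, and endothelial minus mesenchymal genes (−2.24) to 0.340 in the pooled list and 2.18 by covered sequence.

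Motif ratios crossed 1 as follows. Without GC matching NKX2-1 was 1.02, GRHL 0.998, NF1 1.38 and CDX 0.948. With windows of 75 bp on either side AP-1 was 0.881, which was called lower (adjusted exact p = 0.00751), KLF/SP 0.949 and PU.1 0.866. In the stronger 50% AP-1 was 0.948, CDX 0.881 and PU.1 0.904. Without a replicate AP-1 was 0.985 to 0.995, the CArG box 0.939 to 1.05 and NF1 1.70 to 1.89. NF1 was also 1.32 in the pooled list, 1.22 at −log10 q of at least 2 and 2.38 at the peak centre. HNF1 was 0.889 and HNF4A 0.939 at −log10 q of at least 2.

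No paired analysis was possible because the series holds a single group. Depth is unknown, so a peak missing from a list may lie below its detection limit: the weakest decile overlapped the other replicate at 32.6% and 34.3%, and with −log10 q of at least 2 the rise across deciles was 59.3 percentage points.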

Other observations

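The tests of gene number on X, of displaced peaks, of CpG content in parts of the lists and of sequence beside the summit were chosen only after the result was seen, as were the regions and lists named in this part. Some of the large clusters below the first 10 ranks follow. Rank 11 spanned the facing genes Col4a1 and Col4a2, which encode basement membrane collagen chains (chromosome 8, 11248153 to 11419784, 64 peaks over 171.6 kb). Rank 15 ran over Notch1, Egfl7 and Agpat2 (chromosome 2, 26474261 to 26608618, 35 peaks over 134.4 kb) and covered 71.2% of Mir126a and 79.3% of Mir126b, microRNA genes annotated at Egfl7. Rank 18 lay at Rbpms with 64 peaks, rank 30 at the non-muscle myosin gene Myh9 with 28 peaks and rank 33 at Nfib, a transcription factor of lung maturation, with 54 peaks over 130.4 kb. Rank 27 held Hoxb2 to Hoxb7 (chromosome 11, 96283802 to 96354831, 21 peaks). Of the 943 large clusters 82 held no protein-coding TSS. The highest of these was rank 17 (chromosome 9, 48673543 to 48789404, 37 peaks over 115.9 kb). The nearest TSS, at 46.5 kb, was that of Zbtb16, a glucocorticoid-induced zinc finger gene. Ranks 22, 23 and 26 lay 28.1 kb from the TSS of Ptpn1, 88.7 kb from that of Ly86 and 39.9 kb from that of Irf2bp2. These distances are to the TSS, so a cluster can lie inside the gene named.

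Promoter marking followed CpG content, with 16.6%, 57.2% and 86.0% of genes marked in the lowest, middle and highest tercile of the CpG ratio, and several lists stood apart from genes of like CpG content. Of 32 lists 8 lay above and 11 below CpG-matched random lists (two-sided permutation test with Benjamini-Hochberg adjustment). Alveolar type 2 genes were marked at 100% where matched genes gave 38.1%, endothelial genes at 95.5% against 47.7%, and mesenchyme and fibroblast genes at 91.3% against 50.1% (adjusted permutation p = 9.14e-04 for each). Neuron genes were marked at 5.0% against 53.4% and Hox paralogs 9 to 13 at 0% against 73.9% (adjusted permutation p = 9.14e-04 for both). Hox paralogs 1 to 5 did not pass this test (60.0% against 64.002%, adjusted permutation p = 0.99), and neither did Hedgehog and Wnt genes (80.0% against 75.5%, adjusted permutation p = 0.955), which had been marked more often than all other genes.

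Of the patterns seen, 3 were weighed. Apart from a lower signal from X, which would have a biological source, no biological explanation was tested, since the design has 1 group. Chromosome X held 0.223 of the autosomal peak density. Fewer genes and marked promoters do not account for all of it, since X held 1.47 distal peaks per marked gene and the lowest autosome 3.08 (SD between replicates 0.611), and neither does repeat sequence, since outside repeats the density was 0.282 of the autosomal median. A lower signal on X, from the single X of males and X inactivation in females of these mixed pools, may contribute but is not shown: X held 0.631 distal peaks per Mb past a fold of 5.12 (108 peaks), and autosomes 0.591 past a fold of 10.2, a ratio of 1.07. This allows the signal to be lowered 2 times, the upper limit, and with 1.5 times, added after that value was seen, the ratio was 0.417, and at the same fold 0.144, so the size of the loss stays open, as does its source, since fold is relative to a control that was not analysed here and that a single X would lower too.

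Neuroendocrine, airway and blood-cell promoters were marked in 10 of 83 genes, 12.05%. Low CpG content of the airway and blood-cell genes may account for part of this, since random genes matched to these 72 were marked in 27.7%. For all 83 genes the matched mean was 31.8%, and the share lay below the 2.5th percentile, 22.9%, a bound printed in place of the list's percentile after that was seen. Since these lists were joined after their low shares had been seen, that choice favoured a joint share below matched genes. Neuroendocrine genes, which are not CpG-poor (median ratio 0.573), were marked at 0% where the 2.5th percentile of matched genes was 27.3%, and the airway and blood-cell genes at 13.9% where it was 19.4%, although none of their 5 lists passed the test singly (adjusted permutation p from 0.117 to 0.99). Peaks displaced from the TSS by up to 2.5 kb do not account for it, since within that distance 13 genes, 15.7%, held a peak, and 54.3% of all genes did. Larger displacements were not tested for these genes as a set. The share of each cell type in the tissue was not measured and stays open.

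The ratios of AP-1 and C/EBP matches to background were 1.11 and 2.85 in windows at peak centres, and 1.03 and 1.61 at summits. Centre and summit windows were not tested against each other. Base composition alone does not account for fewer matches close to the summit. From the summit (75 bp on either side) to windows 100 to 250 bp away, the reversed consensus of both gave a ratio of 0.936 (95% bootstrap interval 0.878 to 1.003) and the consensus 1.501 (1.41 to 1.61). Taken singly, the ratio of the consensus was 1.483 for AP-1 and 2.67 for C/EBP (1.71 to 4.55), the latter from only 18 summit windows with a match. Whether summits lie beside the bound site stays open, since fewer AP-1 matches close to the summit had already been seen in the same peaks and the higher flank restates this. Binding of these factors was not measured.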
